A study of Homo sapiens with 7 samples.

How the data were processed

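Small RNA was sequenced from HepG2, an established human hepatocellular carcinoma line. Per the labels, 1 library came from untreated cells (0 h) and 6 came from cells treated with either of 2 siRNAs against TEAD1, a DNA-binding transcription factor of the Hippo pathway, for 24, 36 or 48 h. Each siRNA and time has 1 library, so each time has 2 libraries that received different siRNAs. Nothing in the labels says whether the libraries came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical. The labels give no library of cells that received a control siRNA, so transfection, time in culture and loss of TEAD1 cannot be separated. TEAD1 itself is an mRNA, and these libraries do not measure it.

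Per the labels' protocols, RNA was taken with a column kit for total RNA and 2 ug went into an NEB ligation-based small RNA kit. The deposited files hold raw read counts per mature miRNA, 1 file per library, with 2652 miRNAs and 5 summary lines of the kind a read counter adds. The aligner, the counter and the genome build are not given in the sources used here. Each miRNA appears once in a file, and miRNAs with the same mature sequence have separate counts. The counts of 4 tested miRNAs that share their sequence with another, miR-199a-3p and miR-365a-3p among them, are uncertain, since reads of such pairs cannot be told apart. The summary lines were kept out of library sizes and tests. Reads given to no feature made up 56.9% of the untreated library and 73.5% to 86.6% of the siRNA-treated libraries, and reads counted as ambiguous numbered 55 to 246 per library.

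Libraries held 13134601 to 15591345 reads, of which 1920832 to 6171851 were assigned to a miRNA. The untreated library had the most assigned reads, so at an equal CPM its values carry the least counting error. For a miRNA that was low in untreated cells, such as miR-1246, the untreated count is small all the same. A count of 3 reads, the limit that a count of 0 allows, corresponds to 0.560 CPM in the untreated library and up to 1.52 CPM in the siRNA-treated ones. The 95% intervals of CPM values and of shares are exact Clopper-Pearson intervals, and those of the ratios of muscle miRNA rates are exact Poisson intervals. Reads carry no molecular identifiers in the files, so intervals and limits cover counting error only.

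All choices in this paragraph and the next were made before the data were examined. The test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) with TMM factors on the 458 miRNAs with a mean count of at least 10, which hold 99.9% of the miRNA reads. Calls used Benjamini-Hochberg adjusted p-values at a threshold of 0.05. The untreated library and the 3 times entered 1 fit, so that the spread came from the 2 libraries of each time, and the lone untreated library was assumed to vary like them. The contrasts were the mean of the 3 times against untreated, each time against untreated, and 48 h against 24 h. The comparison of siRNA 2 with siRNA 1 used the 6 siRNA-treated libraries and 435 miRNAs, with time as a factor. Each siRNA against untreated was fitted with the siRNA as the group. Standard errors are those for which the squared ratio of log2 fold change to error equals the F statistic. CPM values are edgeR counts scaled by the TMM-adjusted library size, and log2 CPM used a prior count of 2.

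For all times against untreated, the miRNAs named were to be the 10 largest rises and 10 largest falls past the threshold, with a mean count of at least 50 and the same side of untreated in all 6 libraries. Where fewer passed, the smallest p-values filled the places, and the 10 most abundant miRNAs were named as well. For the other comparisons, where none passed, the 3 smallest p-values were named. Members of lists serve as examples of their list, and any other miRNA named was chosen after its values were seen. A set of 23 miRNA lists (families, genomic clusters, liver-enriched miRNAs and markers of blood, muscle, fibroblast, endothelial and neuronal cells) was fixed. The 17 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry.

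Alternatives were DESeq2 1.42.0, limma-voom, the size factors of DESeq2, total counts as the scale, no count filter, a mean count of 50, each siRNA-treated library left out, the siRNA number as a block and other forms of the time term. Removal of a linear GC trend per library, scaling by all reads of a library, and a fit without both 36 h libraries were added after the data were seen. So were the list tests of 48 h against 24 h. The scripts were tested on simulated counts with known changes. For all times against untreated, 31.7% of 2-fold, 73.7% of 4-fold and 98.1% of 8-fold changes were recovered, with 5 false calls among 251 unchanged miRNAs. For 48 h against 24 h the shares were 15.9%, 75.0% and 95.2%, with 1 false call among 252, and for siRNA 2 against siRNA 1 they were 33.8%, 93.8% and 100.0%, with 4 among 247. The count filter was applied again to the simulated counts. After it, 169 of 420, 190 of 442 and 191 of 438 miRNAs were changed ones. The shares leave out changed miRNAs that the filter removed. All libraries were drawn with the same spread for a miRNA, without a 36 h pair that differs more than the others. The shares may thus be too high for these libraries. In a simulation of the list test, a list shifted by 1.5 on the log2 scale passed, and 0 of the other lists did. It was a single data set with miRNAs drawn independently. It cannot show how often unchanged lists pass where members move together. In the data the estimated correlation was 0.89 for the miR-130 and miR-301 family.

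Mature sequences were placed on GRCh38 by exact match within the miRNA hairpins of the GENCODE 29 annotation. Sequences were also searched in its annotated structural RNAs (small nuclear, small nucleolar, ribosomal and mitochondrial), and 16 miRNAs of the files matched one. Figures were drawn with matplotlib 3.10.9.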

Results

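The series asked how miRNA levels in HepG2 cells change as TEAD1 is silenced. It has 7 small RNA libraries: 1 of untreated cells and 2 each at 24, 36 and 48 h of siRNA treatment. The untreated library held 14308482 reads, of which 6171851 were assigned to a mature miRNA. With siRNA 1 the assigned reads numbered 3739729, 1920832 and 2114050 at 24, 36 and 48 h, and with siRNA 2 they numbered 2808944, 2070547 and 2095438. The miRNA share of all reads was 43.1% in the untreated library (95% Clopper-Pearson interval 43.1 to 43.2) and 17.5% ± 4.68 (SD, n = 6) in the siRNA-treated libraries, with a range of 13.4% to 26.5%. Between 955 and 1137 miRNAs had at least 1 read.

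miR-21-5p, an abundant miRNA of many tumour lines, was the largest component in all 7 libraries. It stood at 364113 CPM in untreated cells and 309959 ± 93542 CPM (SD, n = 6) after siRNA treatment. let-7f-5p followed at 132981 against 96051 ± 33189 CPM, then miR-30a-5p at 73214 against 61031 ± 14360 CPM and let-7i-5p at 68922 against 50690 ± 10899 CPM. let-7g-5p stood at 43015 against 29047 ± 8897 CPM, miR-100-5p at 40010 against 46893 ± 14494 CPM, miR-99a-5p at 32313 against 44533 ± 17287 CPM, let-7a-5p at 29583 against 30127 ± 2192 CPM and miR-148a-3p at 18426 against 16807 ± 4497 CPM. The log2 fold changes of these 9 ran from -0.60 ± 0.30 (SE) for let-7g-5p to 0.40 ± 0.38 for miR-99a-5p, and none passed the edgeR test (adjusted p from 0.899 to 0.992).

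**Figure D1:**
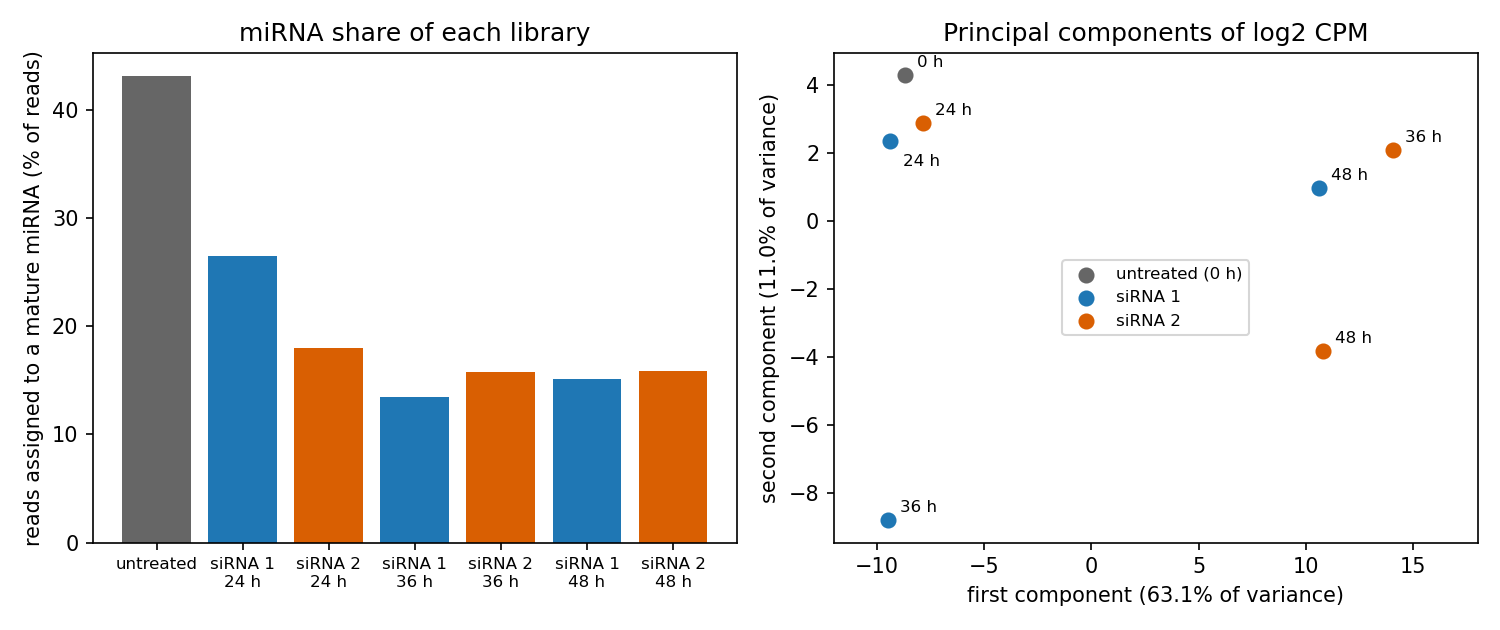
Left, bars give the percentage of all reads assigned to a mature miRNA in each of the 7 libraries, from 43.1% in untreated cells to 13.4% with siRNA 1 at 36 h. Right, each point is a library on the first 2 principal components of log2 CPM, labelled by its time in h, with the siRNA 2 library of 36 h beside both 48 h libraries on the first component (63.1% of variance).

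The first principal component of log2 CPM held 63.1% of the variance. It placed siRNA 1 at 48 h (10.6), siRNA 2 at 36 h (14.05) and siRNA 2 at 48 h (10.8) apart from untreated (-8.70), siRNA 1 at 24 h (-9.36), siRNA 2 at 24 h (-7.86) and siRNA 1 at 36 h (-9.49). The SD over miRNAs of the log2 difference between the siRNAs was 0.57 at 24 h, 1.22 at 36 h and 0.50 at 48 h. The pair of 36 h held 72.0% of the sum of squares within times. The libraries of 36 h thus gave most of the spread against which the other contrasts were tested. A wrong time or sample label for one of them was not ruled out, and each 36 h value and contrast takes the labels as given.

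The first comparison asked which miRNAs differed between siRNA-treated and untreated cells over the 3 times. miR-7-5p, a miRNA known to target EGFR, was lower in 6 of 6 siRNA-treated libraries, at 23985 ± 9169 CPM (SD, n = 6) against 64525 CPM untreated (95% interval 64317 to 64734). Its log2 fold change was -1.50 ± 0.28 (SE), with an adjusted p of 0.256 by edgeR. The opposite arm of one of its hairpins, miR-7-1-3p, stood at 25.9 ± 17.4 against 54.3 CPM. miR-1246 was higher in 6 of 6, at 38.1 ± 14.7 CPM against 3.54 CPM (19 reads, interval 2.13 to 5.53), a log2 fold change of 3.38 ± 0.63 (adjusted p = 0.256). The mature sequence of miR-1246 lies within annotated U2 small nuclear RNAs. miR-143-3p, a miRNA abundant in smooth muscle and fibroblasts, was also higher in 6 of 6, at 441 ± 246 against 159 CPM (1.26 ± 0.31, adjusted p = 0.762).

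None of the 458 miRNAs passed the edgeR test over the 3 times. At an unadjusted p under 0.05 there were 23, where chance gives 22.9, and limma-voom called 0 with 29 at that level. DESeq2 called 1, miR-1246 (log2 fold change 3.46, adjusted p = 3.5e-05). The count rested on the 36 h libraries: without siRNA 1 at 36 h 65 miRNAs passed (17 higher, 48 lower), without siRNA 2 at 36 h 31 passed (12 higher, 19 lower), and without both, in a fit added after the data were seen, 50 passed (17 higher, 33 lower). The 3 fits shared 25 miRNAs, 10 higher and 15 lower. Leaving out any other siRNA-treated library gave 0. Each of these 3 fits drops the pair with the widest spread, and the fit without both was chosen for that spread, so their errors and p-values are too small if that spread is real.

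Among those 25 shared miRNAs, miR-7-5p fell by 1.36 ± 0.20 (SE) on the log2 scale in the fit without the 36 h libraries (edgeR adjusted p = 4.4e-09), in 4 of the 4 siRNA-treated libraries it used. In the same fit miR-452-5p fell by 0.84 ± 0.22, miR-4521 by 1.27 ± 0.25, miR-941 by 0.66 ± 0.22, miR-19a-3p by 1.45 ± 0.27 and miR-675-5p, which is processed from the H19 transcript, by 0.90 ± 0.26. miR-1246 rose by 3.59 ± 0.47 (adjusted p = 3.2e-11), miR-12136 by 2.29 ± 0.43, miR-6866-5p by 1.45 ± 0.35 and miR-143-3p by 0.84 ± 0.29 (adjusted p = 0.0362). The sequence of miR-12136 lies within a mitochondrial transfer RNA, and it is among the structural RNA members taken up further below. miR-122-5p, the main hepatocyte miRNA, fell by 2.32 ± 0.38 and stood at 45.5 CPM untreated. With siRNA 1 it was at 32.2, 47.6 and 4.37 CPM at 24, 36 and 48 h, and with siRNA 2 at 4.60, 6.60 and 3.76 CPM. With total counts as the scale 27 passed in that fit (12 higher, 15 lower), and the median of all miRNAs moved to 0.13. Scaling by all reads moved the median of all miRNAs to -1.09 and gave 196 (4 higher, 192 lower).

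The other miRNAs named by the rule did not pass in the full fit (adjusted p = 0.899 each). On the higher side, with 6 of 6 libraries above untreated, were miR-12136 (2.44 ± 0.89 SE), miR-6866-5p (1.58 ± 0.60), miR-451a (1.26 ± 0.67), miR-324-5p (0.77 ± 0.37), miR-200c-3p (0.67 ± 0.43), miR-532-3p (0.63 ± 0.40), miR-1296-5p (0.59 ± 0.35) and miR-424-3p (0.50 ± 0.33). On the lower side, with 6 of 6 below, were miR-19a-3p (-1.46 ± 0.58), miR-4521 (-1.22 ± 0.43), miR-500a-5p (-1.04 ± 0.38), miR-452-5p (-0.90 ± 0.29), miR-675-5p (-0.88 ± 0.36), miR-185-5p (-0.74 ± 0.29), let-7a-3p (-0.73 ± 0.30), miR-941 (-0.69 ± 0.25) and miR-330-3p (-0.69 ± 0.26). miR-451a is an erythroid miRNA and had 63 reads in the untreated library. Over all tested miRNAs, 47 lay above and 62 below untreated in all 6 libraries, where 7 exchangeable libraries would give 65.4 of each, so the same side in 6 of 6 is by itself no evidence of a change.

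**Figure D2:**
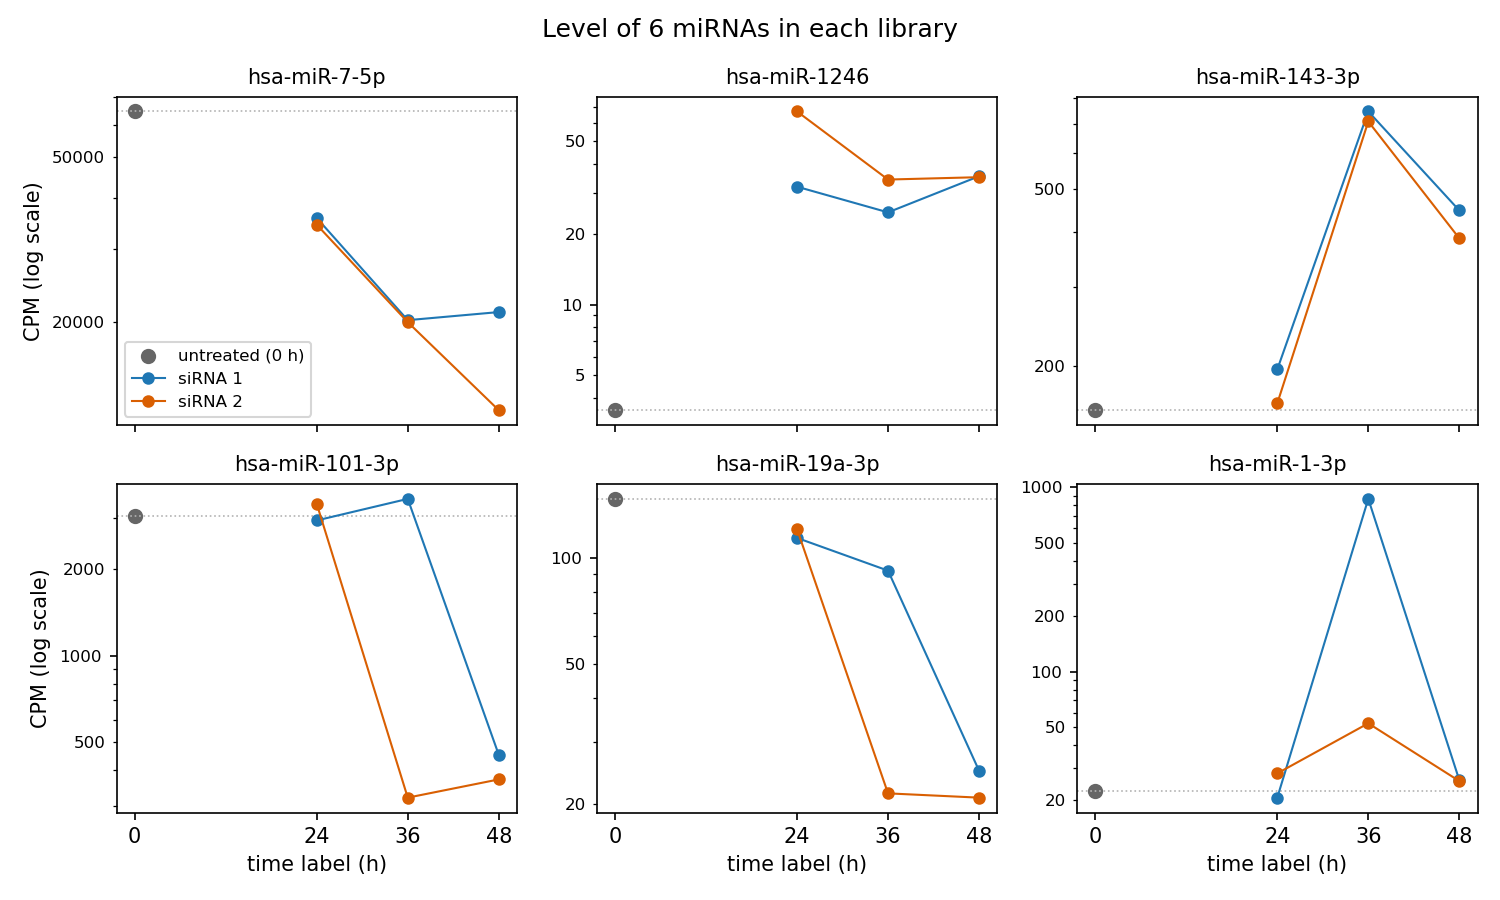
CPM (log axis) of 6 miRNAs in each of the 7 libraries against the time label in h, with 1 point per library, lines joining the libraries of a siRNA and a dotted line at the untreated level. miR-7-5p lies below and miR-1246 above the untreated level in all 6 siRNA-treated libraries, miR-101-3p and miR-19a-3p differ between the siRNAs at 36 h, and miR-1-3p stands at 867 CPM with siRNA 1 at 36 h.

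On GRCh38 miR-7-5p has 3 hairpins. MIR7-1 holds it at chromosome 9, 83969811 to 83969834, in an exon of HNRNPK. MIR7-2 holds it at chromosome 15, 88611856 to 88611879, between genes, and MIR7-3 at chromosome 19, 4770700 to 4770723, in an intron of MIR7-3HG. miR-1246 lies at chromosome 2, 176601024 to 176601042, between genes, and miR-143-3p at chromosome 5, 149428978 to 149428998, in an exon of the long noncoding RNA CARMN. miR-19a-3p lies at chromosome 13, 91350939 to 91350961, in an exon of MIR17HG. miR-122-5p lies at chromosome 18, 58451088 to 58451109, in an exon of MIR122HG.

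Of the 17 fixed lists tested over the 3 times, the markers of fibroblasts and endothelium were higher by camera (adjusted p = 0.0193). The adjusted p was 0.764 with an estimated correlation and 0.0344 by fry. This list has 4 tested members: miR-143-3p, miR-126-3p (337 ± 67.4 CPM after siRNA), miR-199a-3p (5.34 ± 1.19 CPM) and miR-199a-5p (5.04 ± 3.20 CPM). None of them passed over all miRNAs and 1, miR-143-3p, passed adjusted over the list alone. With a mean count of 50 this list was not tested, since miR-199a-3p and miR-199a-5p fell below it and fewer than 3 members remained. Without siRNA 1 at 36 h this list did not pass. That library stood apart with 867 CPM of the muscle miRNA miR-1-3p and held the highest value of miR-199a-5p, 11.1 CPM against 1.49 to 5.78 CPM in the other 6.

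The miR-17~92 cluster, a set of growth-promoting miRNAs processed from MIR17HG, had a median log2 fold change of -0.71 over its 9 members (adjusted p = 0.162 by camera, 0.865 with an estimated correlation). Of these, 7 were below 0, among them miR-20a-5p at 2035 ± 1308 CPM against 3636 CPM untreated. miR-92a-3p stood at 17378 ± 3833 CPM, with a log2 fold change of 0.20 ± 0.32. This list passed without siRNA 1 at 36 h (adjusted p = 0.0119), without siRNA 2 at 36 h (0.0237) and with total counts as the scale (0.0413).

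The other lists did not pass (0 called at the preset correlation, and 0 of their members over all miRNAs or adjusted over the list alone). Among them, medians were 0.67 for the miR-200 family (3 of 3 above 0), 0.46 for markers of neurons, 0.20 for the miR-10, miR-99, miR-100 and miR-125 group, 0.15 for the miR-29 family and 0.10 for the miR-181 family, whose mean was -0.06. The neuron list names miR-137, which appears in these data as miR-137-3p. That miRNA passed the count filter but was left out of the 3 tested members of the list. The let-7 family had a median of 0.02 and a mean of -0.14, with 5 members above and 4 below 0. The inflammatory and interferon-linked list had a median of 0.05, and the miR-15/16 family -0.02. With all reads as the scale, which moved the median of all miRNAs to -1.13, the medians of all 17 tested lists were below 0. With total counts, which moved it to 0.19, the medians of 6 lists given here as below 0 were above 0: 0.20 for miR-15/16, 0.18 for miR-232724, 0.14 for miR-30, 0.12 for miR-221 and miR-222, 0.08 for liver-enriched miRNAs and 0.03 for miR-106b~25. Those of miR-15/16 and miR-232724 were also above 0 with DESeq2 size factors. The direction given by camera was lower for the let-7 family and higher for the miR-15/16 and miR-181 families. Medians were -0.05 for the miR-232724 clusters, -0.09 for the miR-30 family, -0.13 for the miR-221 and miR-222 cluster, -0.15 for liver-enriched miRNAs, -0.21 for the miR-106b~25 cluster, -0.37 for the miR-183, miR-96 and miR-182 cluster and -0.49 for the miR-130 and miR-301 family. Lists with fewer than 3 tested members were not tested: miR-34 (2 members, median 0.55, with miR-34c-5p at 40.5 CPM with siRNA 1 at 36 h against 1.31 to 5.86 CPM in the other siRNA-treated libraries), C19MC (2, 0.02), hypoxia-linked (1, miR-210-3p at 0.43), blood cells (1, miR-451a at 1.26), muscle (1, miR-1-3p at 1.54, and at 0.20 without the 36 h libraries) and the 14q32 cluster (0).

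Each time was then compared with untreated cells. At 24 h, miR-1246 stood at 31.9 and 66.9 CPM with siRNA 1 and siRNA 2 (log2 fold change 3.78 ± 0.67 SE, edgeR adjusted p = 0.377). miR-1260b stood at 6.50 and 7.95 CPM against 33.2 CPM untreated (-2.20 ± 0.62, adjusted p = 0.997), and miR-941 at -0.76 ± 0.30 (0.997). edgeR called 0 of 458 with 11 at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called miR-1246. Without siRNA 1 at 36 h 5 passed, without siRNA 2 at 36 h 14, and without both 13 (9 higher, 4 lower), 5 of them in all 3 fits. The last fit gave 4 higher and 3 lower with total counts and 2 higher and 6 lower with all reads. The 13 included miR-1260b, which fell by 2.15 ± 0.39, miR-7-5p, which fell by 0.82 ± 0.23, and let-7b-3p, which fell by 1.42 ± 0.32.

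At 36 h, miR-143-3p reached 746 and 708 CPM with siRNA 1 and siRNA 2, against 159 CPM untreated. Its log2 fold change was 2.19 ± 0.35 (SE), with an adjusted p of 0.217 by edgeR and 2.4e-05 by DESeq2. miR-7-5p had a log2 fold change of -1.68 ± 0.34 and miR-1246 of 3.05 ± 0.65, both with an adjusted p of 0.360 by edgeR. edgeR called 0 with 19 at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 7 (6 higher, 1 lower). With siRNA 2 as the lone 36 h library 91 passed, and with siRNA 1 as the lone one 14 passed, the lone library being assumed to vary like the others.

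At 48 h, miR-7-5p stood at 21190 and 12292 CPM with siRNA 1 and siRNA 2 (log2 fold change -1.95 ± 0.34 SE, edgeR adjusted p = 0.367). miR-1246 was at 3.30 ± 0.66 and miR-143-3p at 1.39 ± 0.34, with the same adjusted p. edgeR called 0 with 53 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2 called 12, 6 higher and 6 lower, with miR-542-3p, miR-340-5p, miR-19a-3p, miR-671-5p, miR-4521 and miR-7-5p on the lower side. Without siRNA 1 at 36 h 94 passed, without siRNA 2 at 36 h 113, and without both 117 (45 higher, 72 lower), 91 of them in all 3 fits. The split in the last fit depended on the scale: 74 higher and 41 lower with total counts, and 5 higher and 180 lower with all reads.

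The comparison of 48 h with 24 h asked how the profile moved over time among siRNA-treated cells, and it does not involve the lone untreated library. miR-1260b stood at 90.4 and 101 CPM at 48 h against 6.50 and 7.95 CPM at 24 h, a log2 fold change of 3.73 ± 0.58 (SE), with an adjusted p of 0.170 by edgeR and 2.5e-07 by DESeq2. miR-143-3p (1.21 ± 0.26) and miR-4443 (2.02 ± 0.51) had an adjusted p of 0.244 by edgeR. miR-101-3p, a miRNA known to target EZH2, stood at 453 and 372 CPM at 48 h against 2939 and 3355 CPM at 24 h (-2.93 ± 0.94, 0.244), and at 3491 and 322 CPM with siRNA 1 and siRNA 2 at 36 h. miR-1260b lies at chromosome 11, 96341447 to 96341465, between genes. miR-101-3p has a locus between genes at chromosome 1, 65058442 to 65058462, and another at chromosome 9, 4850345 to 4850365, in an intron of RCL1.

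edgeR called 0 of 458 for 48 h against 24 h with 84 at an unadjusted p under 0.05, limma-voom called 0 with 83, and DESeq2 called 23 (6 higher, 17 lower). Without siRNA 1 at 36 h 122 passed, without siRNA 2 at 36 h 131, and without both 134 (51 higher, 83 lower), and 121 passed in all 3 fits. The split without both depended on the scale: 105 higher and 55 lower with total counts, which moved the median of all miRNAs to 0.34, and 7 higher and 52 lower with all reads, which moved it to -0.16. With TMM the median was -0.01.

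In the fit without the 36 h libraries, whose p-values are too small if the spread of that pair is real, 6 of 9 members of the miR-17~92 cluster fell from 24 h to 48 h: miR-19b-3p by 2.43 ± 0.28 (SE), miR-19a-3p by 2.37 ± 0.29, miR-18a-5p by 1.90 ± 0.34, miR-20a-5p by 1.84 ± 0.22, miR-17-3p by 1.38 ± 0.47 and miR-17-5p by 1.05 ± 0.21. miR-92a-3p stood at 0.41 ± 0.20 and did not pass (adjusted p = 0.105). Of the miR-130 and miR-301 family 4 of 5 fell, among them miR-301a-3p by 2.67 ± 0.40 and miR-454-3p by 1.09 ± 0.24. The abundant let-7f-5p, let-7g-5p and let-7i-5p fell with miR-98-5p, 4 of 9 let-7 members, by 0.94, 0.75, 0.67 and 0.73, while let-7a-5p and let-7b-5p did not pass. None of these let-7 members passed with total counts, where let-7f-5p stood at -0.59 ± 0.28, or with all reads, where it stood at -1.15 ± 0.45 (adjusted p = 0.0676) and let-7i-5p at -0.87 ± 0.45. For let-7f-5p and let-7i-5p, the larger errors with all reads, not smaller changes, thus ended the calls. let-7b-5p rose with total counts. Of the miR-17~92 cluster 5 fell and 2 rose with total counts, 6 fell and 1 rose with DESeq2 size factors, and 4 fell and 0 rose with all reads. The first principal component had both 48 h libraries at its higher end. On it the loading, or weight, of miR-18a-5p was -0.098 and that of its opposite arm miR-18a-3p 0.038. Those of miR-17-5p and miR-17-3p were -0.056 and -0.067. A sequence-linked part of that component is taken up further below, so these falls need not be changes of the whole cluster.

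Of the miR-10, miR-99, miR-100 and miR-125 group, 3 of 7 rose in that fit: miR-99a-5p by 1.08 ± 0.20 (SE), from 30528 and 26285 CPM at 24 h to 59507 and 61596 CPM at 48 h, miR-125a-5p by 0.83 ± 0.22 and miR-100-5p by 0.58 ± 0.20. None of the 7 passed with all reads, where miR-99a-5p stood at 0.88 ± 0.46. The opposite arms miR-99a-3p and miR-100-3p had loadings below 0 on the first principal component (-0.042 and -0.103), and miR-125a-3p had one above 0 (0.0052). Among liver-enriched miRNAs, miR-101-3p fell by 2.95 ± 0.23, miR-122-5p fell by 2.22 ± 0.47 and miR-192-5p rose by 0.55 ± 0.21. miR-143-3p of the fibroblast and endothelium markers rose by 1.19 ± 0.25, miR-451a of the blood markers by 1.51 ± 0.38 and miR-128-3p of the neuron markers by 0.95 ± 0.21. miR-21-5p and miR-21-3p, the 2 of 7 passing members of the inflammatory list, fell by 0.57 ± 0.20 and 1.46 ± 0.24. On the lower side, passing members of the other lists numbered 2 of 6 for miR-29 and 2 of 4 for the miR-183, miR-96 and miR-182 cluster. There were 3 of 8 for miR-30, 1 of 7 for miR-15/16 and 1 of 6 for miR-106b~25. The miR-232724 list had 1 higher and 2 lower, and the miR-221 and miR-222 cluster had 1 of each. On the higher side were 1 of 3 for miR-200, 1 of 5 for miR-181 and the hypoxia-linked miR-210-3p. Over all miRNAs of that fit 134 of 467 passed, 51 higher and 83 lower. No list was tested against that share, so counts of a few members do not by themselves set a list apart.

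With all libraries, camera on 48 h against 24 h called 1 list, a test chosen after the data were seen. The miR-130 and miR-301 family was lower (median log2 fold change -1.08, 5 of 5 below 0, adjusted p = 0.0400), and the adjusted p was 0.640 with an estimated correlation. The miR-17~92 cluster had a median of -1.36 (7 of 9 below 0, adjusted p = 0.0872). The other 15 lists did not pass.

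The 2 siRNAs were compared with each other across the 3 times. miR-122-5p was lower with siRNA 2, at 4.99 ± 1.46 CPM (SD, n = 3) against 28.1 ± 21.9 CPM with siRNA 1, a log2 fold change of -2.09 ± 0.65 (SE) with an adjusted p of 0.992 by edgeR. miR-4521 (-0.71 ± 0.27) and miR-7706 (0.85 ± 0.35) had the same adjusted p. None of the 435 miRNAs passed by edgeR, limma-voom or DESeq2, and 6 had an unadjusted edgeR p under 0.05, where chance gives 21.75.

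Against untreated cells, siRNA 1 gave 30.7 ± 5.40 CPM of miR-1246 (SD, n = 3; log2 fold change 3.10 ± 0.63 SE, edgeR adjusted p = 0.688) and siRNA 2 gave 45.4 ± 18.6 CPM (3.66 ± 0.65, 0.305). miR-7-5p stood at 25722 ± 8668 CPM with siRNA 1 (-1.33 ± 0.55, adjusted p = 0.999) and at 22249 ± 11225 CPM with siRNA 2. miR-24-2-5p was at -0.76 ± 0.29 with siRNA 1, miR-452-5p at -1.04 ± 0.35 and miR-122-5p at -3.18 ± 0.94 with siRNA 2, with adjusted p-values of 0.999 for siRNA 1 and 0.899 for siRNA 2. edgeR called 0 for either siRNA, with 8 and 22 at an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called miR-1246 for each. Over miRNAs, which are not independent replicates, the 2 sets of fold changes had a Pearson r of 0.85, where unchanged groups sharing the untreated library gave 0.73 (range of the central 95% 0.68 to 0.80). Their covariance was 0.40 against a simulated 0.43 (0.34 to 0.55), and 84.7% had the same sign against 76.4%. The simulated libraries were drawn independently, without the movement over time that both siRNA groups share. Such movement can raise r and the share of equal signs, so the excess over the simulation does not show an effect common to the siRNAs.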

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

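The tests of muscle RNA and of fragments of structural RNAs were chosen after the results were seen, as were the removal of the GC trend and the fit without the 36 h libraries. Single libraries that stood far from the other siRNA-treated libraries were sought among 127 quantities, each over the 6 siRNA-treated libraries, and 8 were found where chance gives 6.35.

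miR-1-3p, a muscle miRNA, stood at 867 CPM with siRNA 1 at 36 h, against 20.7 to 52.4 CPM in the other 5 siRNA-treated libraries and 22.6 CPM untreated. Of the other muscle miRNAs, without the look-alike miR-206, that library held 14 reads and the other 6 libraries together 21, a rate ratio of 6.59 (95% exact Poisson interval 3.10 to 13.6). Those 14 were 9 of miR-499a-5p and 5 of miR-133a-3p, which shares host transcripts with miR-1-3p, with 0 of miR-133b, miR-208a-3p and miR-208b-3p, beside 1713 reads of miR-1-3p and 13 of miR-206 (0 or 1 in each other library). A small amount of RNA from muscle may account for this. A source of miR-1-3p alone would not raise miR-499a-5p, whose rate ratio was 7.42 (95% exact Poisson interval 2.76 to 19.2). That of miR-133a-3p was 6.18 (1.59 to 21.4). These ratios rest on few reads of 1 library. No muscle profile was at hand to say how many reads of these miRNAs muscle RNA would bring. No biological explanation was tested, since the design has 1 library per siRNA and time.

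The other single libraries were all the highest of their 6. miR-1246 stood at 66.9 CPM with siRNA 2 at 24 h, against 24.8 to 35.4 CPM in the others. miR-148a-3p stood at 25536 CPM in the same library, against 13927 to 17522 CPM. miR-194-5p stood at 136 CPM with siRNA 1 at 36 h, against 68.6 to 90.4 CPM. miR-34c-5p stood at 40.5 CPM in that library, against 1.31 to 5.86 CPM. miR-210-3p stood at 359 CPM with siRNA 2 at 48 h, against 143 to 204 CPM. miR-4443 stood at 100.2 CPM in that library, against 15.1 to 38.5 CPM. The miRNA share of reads was 26.5% with siRNA 1 at 24 h, against 13.4% to 18.02%.

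Over all 458 tested miRNAs, 48 lay below the untreated level in both 24 h libraries and above it in both 48 h libraries, and 34 the other way round, where exchangeable libraries would give 15.3 of each. Of the 34 miRNAs named by the rule 4 were below and then above, miR-4443 with siRNA 1 at 24 h only just (18.9 against 19.02 CPM untreated). Against untreated, no miRNA passed by edgeR with all libraries at 24 h or at 48 h, and a joint test of opposite directions was not run. The difference between 48 h and 24 h did not pass by edgeR with all libraries for these 4: log2 fold change 3.73 ± 0.58 (SE, adjusted p = 0.170) for miR-1260b, 2.02 ± 0.51 (0.244) for miR-4443, 1.09 ± 0.35 (0.244) for miR-99a-5p and 0.60 ± 0.35 (0.393) for miR-100-5p. It passed without the 36 h libraries, which restates the pattern by which they were picked.

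Reads given to no feature lie outside the comparisons. They made up 73.5% of reads in the siRNA-treated library with the fewest of them, against 56.9% in the untreated library. Their origin was not analysed here.

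miR-1246 and miR-4485-3p, whose sequences lie within U2 small nuclear RNAs and the mitochondrial 16S ribosomal RNA, were above the untreated level in 6 of 6 libraries, miR-4485-3p with 10.3 ± 5.83 CPM (SD, n = 6) against 3 reads untreated. For miR-1246, lower counts in the siRNA-treated libraries were argued against. Its mean log2 difference stayed at 3.09 (2.12 to 3.74 over 20 thinnings) with all libraries thinned to the smallest total. This was not examined for miR-4485-3p. The other 6 tested miRNAs within annotated structural RNAs had a median log2 fold change of 0.95, against -0.05 for the rest (one-sided permutation p = 0.00046, 100000 draws, and 0.00097 with 1 value for each of 5 host RNAs), though none of the 6 passed by edgeR (adjusted p of 0.899 or more). These p-values take miRNAs as independent, while every fold change rests on the lone untreated library, the lowest of 7 in the median of the 6, and the smallest p that 1 library of 7 allows is 0.143. More fragments of longer RNAs among the reads may account for these miRNAs, and an effect of TEAD1 loss stays open and untested.

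The first principal component, with 63.1% of the variance (bootstrap interval 58.2 to 68.2), set both 48 h libraries and the siRNA 2 library of 36 h apart from the rest. Unequal depth was argued against by its share of 61.4% after thinning, and a linear GC trend as the whole cause by its share of 58.6% (53.3 to 64.0) after that trend was removed. A GC trend was still part of the pattern, with a Spearman correlation of 0.37 between loadings and GC content. Differences from untreated correlated with GC content at 0.30 (siRNA 1, 48 h), 0.36 (siRNA 2, 36 h) and 0.30 (siRNA 2, 48 h). The other siRNA-treated libraries gave -0.11 (siRNA 1, 24 h), 0.02 (siRNA 1, 36 h) and -0.07 (siRNA 2, 24 h). Loadings of the 5p and 3p arms of 97 hairpins had a Pearson r of 0.084 (-0.13 to 0.29), over miRNAs that are not independent. This argues against a change in the amount of each hairpin as the whole cause. A linear model on base composition and end bases gave an R2 on held-out miRNAs of 0.227 (0.20 to 0.24), between the bounds set in advance, so a sequence-dependent step in library preparation may contribute and cannot be told apart from changes specific to mature strands. Time after siRNA treatment stays open, with the siRNA 1 library of 36 h on the side of the 24 h libraries, as does a wrong time or sample label for a 36 h library, which was not tested.

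For siRNA 2 against siRNA 1, 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 0 miRNAs and the highest other split 112. With time as a factor, the splits with 112 compare only the 36 h libraries with each other.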

How the results depend on the processing

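The GC trend removed, all reads as the scale and the fit without the 36 h libraries were chosen after the results were seen. With 0 miRNAs called by edgeR in the 8 comparisons (23, 11, 19, 53, 84, 6, 8 and 22 at an unadjusted p under 0.05, in the order of the report), DESeq2 size factors, total counts, limma-voom, a mean count of 50 and the other forms of the time and group terms also gave 0.

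DESeq2 called 1 miRNA for knockdown against untreated, 1 at 24 h, 7 at 36 h, 12 at 48 h, 23 for 48 h against 24 h and 1 for each siRNA. Without a count filter 12, 2, 10, 39, 51, 3 and 8 passed in that order, and with all reads as the scale 120, 2, 49, 118, 29, 0 and 1. The cause was not tested, apart from the shift of all miRNAs with all reads (median -1.13 for knockdown). With the GC trend removed 1 miRNA, miR-1260b, passed for 48 h against 24 h. Without the 36 h libraries 50, 13, 117 and 134 passed for knockdown, 24 h, 48 h and 48 h against 24 h. Leaving out 1 library gave 0 to 65 for knockdown, 0 to 14 at 24 h, 0 to 91 at 36 h, 0 to 113 at 48 h and 0 to 131 for 48 h against 24 h. Each count above 0 came from leaving out a library of 36 h: without siRNA 1 at 36 h 65, 5, 91, 94 and 122, and without siRNA 2 at 36 h 31, 14, 14, 113 and 131. That pair held 72.0% of the sum of squares within times. The 3 comparisons by siRNA gave 0 with any 1 library left out.

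Of the lists for knockdown, 1 passed. With an estimated correlation 0 passed, with a mean count of 50 0, with total counts 2 and with 1 library left out 1 to 2. The cause was not tested.

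Of 828 alternatives for 50 named results, 696 kept their direction and side of the threshold, 119 passed the threshold in the same direction and 13 reversed, none of them called in the full fit. With all reads as the scale, log2 fold changes for knockdown became -0.34 for miR-324-5p, -0.50 for miR-1296-5p, -0.44 for miR-532-3p, -0.41 for miR-200c-3p, -0.58 for miR-424-3p, -0.85 for miR-100-5p, -0.66 for miR-99a-5p and -1.05 for let-7a-5p. let-7a-5p also became -0.062 without a count filter and ran from -0.012 (without siRNA 1 at 24 h) to 0.083 (without siRNA 2 at 24 h) with 1 library left out. miR-148a-3p became 0.080 with total counts, 0.023 with the GC trend removed and 0.022 without the 36 h libraries. The cause was not tested.

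The siRNA number as a block gave 0 calls in the 5 comparisons that took it. Over miRNAs the difference between siRNAs had r of 0.096, -0.25 and -0.16 between pairs of times, so the numbers do not pair the libraries. With no repeated names in the files, summing repeated entries was not run. Depth limits low miRNAs most, with 3 reads at 0.560 CPM untreated and 1.52 CPM with siRNA 1 at 36 h.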

Other observations

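The list tests of 48 h against 24 h and the fit without the 36 h libraries were chosen after the results were seen, and the p-values of that fit are too small if the spread of the 36 h pair is real. Among miRNAs outside the lists, chosen here after their values were seen, those that fell from 24 h to 48 h in that fit included miR-542-3p, by 3.68 ± 0.32 (SE), miR-374a-3p, by 3.31 ± 0.25, and miR-340-5p, by 2.99 ± 0.24. miR-374a-3p stood at 1234 and 1220 CPM with siRNA 1 and siRNA 2 at 24 h and at 149 and 102 CPM at 48 h. On the other side, miR-615-3p, which lies in the HOXC cluster, rose by 1.80 ± 0.24, from 145 and 202 CPM to 582 and 637 CPM, and miR-139-5p rose by 1.30 ± 0.24. None of these passed by edgeR in the fit with all libraries, and DESeq2 called miR-542-3p, miR-340-5p and miR-615-3p there. On the first principal component the loading of miR-340-5p was -0.148 and that of its opposite arm miR-340-3p 0.035. Both arms of miR-374a (-0.084 and -0.167) and both of miR-139 (0.070 and 0.015) shared a sign. The sequence-linked part of that component, taken up above, may contribute to these differences.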
